A study of Mus musculus with 4 samples.

How the data were processed

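Gene expression was measured in full-thickness back skin of male mice aged 42 days, labelled as being in telogen, the resting phase of the hair cycle. One group, called cKO below, lacked Fgf18 in keratin 5-positive epithelium, and the other, called WT below, was C57BL/6. Per the labels, polyA RNA of 3 mice was pooled for each genotype, and each pool was hybridised to 2 one-colour arrays after Cy3 labelling of 200 ng RNA. Each genotype was therefore represented by 1 pool, and the 2 arrays of a group were technical duplicates of it. All standard deviations, standard errors and p-values given here measure the spread between duplicate arrays. The tests compared 2 RNA pools and not the genotypes, because the spread between mice was not measured.

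The arrays were scanned and quantified with Agilent Feature Extraction 10.7.3.1, per the file headers, which record background subtraction and detrending within each array. The deposited spot intensity after these steps was the starting value. The deposited processed values were found to be that intensity divided by 1 number per array, so that they were a linear ratio to the 75th percentile as the authors' scaling left them, not centred per gene. The column medians were 0.101 and 0.0983 for the cKO arrays and 0.0987 and 0.101 for the WT arrays. They were used as an alternative. The tool used for that scaling is not given in the sources used here. All 4 arrays lay on 1 slide with 1 scan time, so slide and scan could not be fitted as a batch.

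Each array held 43379 non-control spots for 41174 probes. Control spots were left out. The log2 of the processed intensity was taken and the 75th percentile of each array over its non-control spots was subtracted. Spots marked as non-uniform (8 and 3 on the cKO arrays, 11 and 18 on the WT arrays) or as population outliers (118, 71, 110 and 126 in the same order) were treated as missing, and spots of one probe were averaged. No spot was saturated. A probe was kept if it was well above background on both arrays of at least 1 group. A gene was represented by its kept probe with the highest mean over the 4 arrays, which left 17555 genes. Scanner-file names were updated through a RefSeq gene table of assembly GRCm38.p6, used for names only. Of the probes, 26690 were named by accession, 5189 by symbol and 952 by an older symbol, and 8343 kept the name in the file. Coordinates are those of the scanner files, on mm9. No gene models of mm9 were used here, so the exon or untranslated region under a probe is not stated.

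The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes tested), without covariates. A gene was called higher or lower at an adjusted p under 0.05 and a change of at least 1.5-fold. The words rose and fell are used only for called genes. Where the probe was not well above background on either array of a group, the change of a named gene in the main fit is given as at least N-fold. This bound is the brighter group's mean against the mean of, per array, the higher of the lowest signal well above background and the probe's own signal. Data handling also used data.table (version 1.17.8), Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

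Before the data were examined, 16 pathway lists and 14 cell type lists were fixed. For each list the median log2 change of its measured genes was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list of at least 5 measured genes stood apart if its median lay under the 2.5th or over the 97.5th percentile. This percentile describes these 2 pools and is no p-value. Some genes are held by more than 1 list. The genes named were also chosen by a rule fixed in advance: Fgf18, the 10 largest rises and 10 largest falls among called genes well above background on all 4 arrays, up to 5 bounded genes per direction, up to 4 called members of each list with the largest change, up to 2 of the brightest members where none was called, all measured FGF ligands, receptors and ERK feedback genes, and Krt5, Krt14, Actb and Gapdh. A few genes that the rule selects are not reported here. Any other gene named was chosen after its values were seen.

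Alternatives were normexp background correction with an offset of 50 followed by quantile normalization, quantile normalization alone, scaling on the median or on probes well above background on all arrays, the authors' processed values, no filter or a stricter filter on dim probes, the mean of a gene's probes, outlier spots kept, an intensity trend with robust estimation, a replicate block, and leaving out each array. The self-test simulated the comparison of the cKO and WT pools over 17555 genes. Calls recovered 37.3% of 67 genes changed 1.5-fold, 88.1% of 67 changed 2-fold and 90.9% of 66 changed 4-fold, with 5 false calls. A 1.5-fold change equals the call threshold and can miss it by noise alone, and 71.6% of those genes passed by adjusted p alone. The changed genes were drawn from those well above background on all 4 arrays, with the spread of duplicate arrays. They were far fewer than the genes passing by adjusted p alone in the data (3890 higher and 5907 lower). The adjustment was therefore stricter in the self-test, and spread between mice was not simulated. Its recovery rates and false calls do not carry over to the calls in the data. In the self-test, 3 of 29 unshifted lists lay outside the percentile limits. The number of arrays limits the precision.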

Results

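The data were 4 one-colour arrays of back skin RNA, 2 of the cKO pool and 2 of the WT pool, each pool made from 3 male mice aged 42 days. The question in the study's design was which genes respond to Fgf18, a secreted fibroblast growth factor, in telogen skin. The 75th percentile of the processed signal was 1403 and 1453 on the cKO arrays and 1271 and 1316 on the WT arrays. Between 62.1% and 69.1% of non-control spots were well above background. Across genes, duplicate arrays correlated at r = 0.997 for cKO and 0.996 for WT, and the highest correlation between arrays of different pools was 0.964. Genes are not independent replicates, and these values describe the arrays only. The median absolute difference between duplicates was 0.041 (cKO) and 0.043 (WT) on the log2 scale, against a median absolute change of 0.19 between pools.

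Fgf18 itself was well above background on all 4 arrays and was slightly lower in the cKO pool. Its processed signal was 5096 and 5293 on the cKO arrays and 5748 and 6076 on the WT arrays. The scaled log2 level was 1.86 ± 0.0026 in cKO and 2.19 ± 0.022 in WT (SD, n = 2 arrays of 1 pool each), a log2 change of -0.33 (SE 0.025, limma adjusted p = 0.0035), or 1.26-fold lower. The gap between the nearest cKO and WT arrays, 0.31, exceeded the larger gap between duplicates, 0.031. The change was under 1.5-fold and was not called, and 16.6% of all genes tested had a log2 change as low or lower. The probe (NM_008005) lies on chromosome 11 from 33017441 to 33017500 on mm9. The labels do not say which part of the gene was deleted, and whole skin also holds cells outside the keratin 5-positive epithelium, so this probe does not check the labels. Keratin 5, which marks the targeted epithelium, had a log2 change of -0.09 (adjusted p = 0.23), and Krt14 had 0.31 (adjusted p = 0.0078). The common reference genes had -0.50 (Gapdh) and -0.16 (Actb), neither past the fold threshold.

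**Figure D1:**
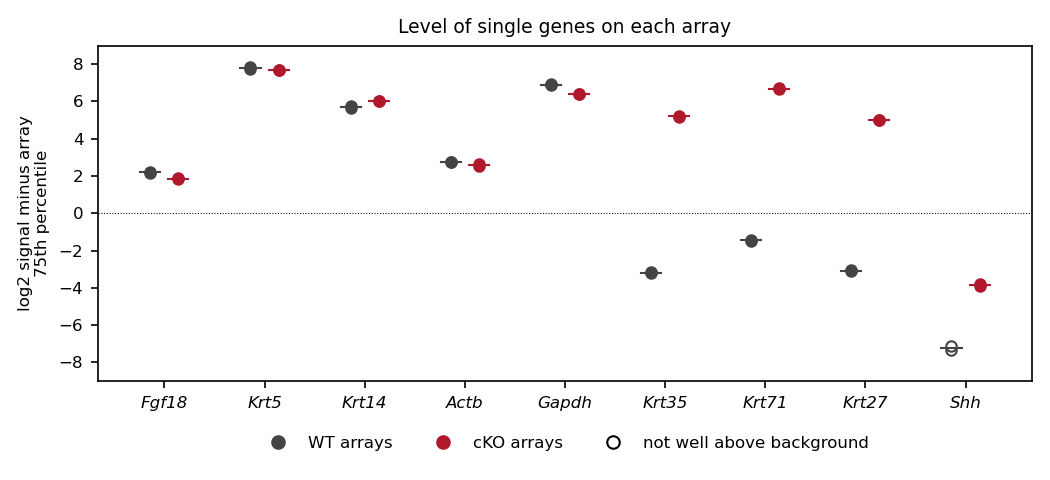
Scaled log2 signal (array 75th percentile at 0) of 9 genes on each WT array (grey) and cKO array (red); short lines are the means of 2 arrays of 1 pool, and open points are spots not well above background. Fgf18 sat at 1.86 in cKO and 2.19 in WT, while Krt35, Krt71 and Krt27 were 8.40, 8.13 and 8.09 log2 units higher in cKO.

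The cKO pool differed from the WT pool above all in genes of the growing hair follicle, in which the largest rises exceeded 10 log2 units. In all, 996 genes rose and 847 fell among 17555 tested. Of these, 216 of the risen genes were not well above background on either WT array, and 17 of the fallen genes were not on either cKO array. At 2-fold the split was 515 higher and 150 lower. The 10 largest rises among genes well above background on all arrays were all keratins or keratin-associated proteins. Krtap22-2, Krtap6-1 and Krtap16-3, which form the matrix between keratin filaments of the hair shaft, rose by log2 10.86 (SE 0.069), 10.45 (SE 0.025) and 10.28 (SE 0.041). Krtap8-1 (9.30), Krtap6-3 (8.48) and Krtap5-1 (8.31) followed, with the shaft keratins Krt33a (8.58) and Krt35 (8.40) and the inner root sheath keratins Krt71 (8.13) and Krt27 (8.09). With normexp and quantile normalization the log2 changes of Krtap22-2, Krtap16-3, Krtap8-1, Krt33a and Krtap5-1 were 9.49, 9.53, 8.47, 7.91 and 7.71, and with the mean of probes Krtap8-1 had 10.15. The adjusted p of these 10 genes lay between 3.65e-05 and 0.00064. Krtap22-2 was near the background limit in WT, with scaled log2 levels of -5.02 and -4.86. Those of Krt25, given below as a bound, were -5.13 and -5.01. The size of the Krtap22-2 rise is therefore less certain than its SE makes it look. Krt71 (chromosome 15, from 101564426 on mm9) was 279-fold higher, and Krt35 (chromosome 11, from 99953539) was 337-fold higher. Among genes not well above background in WT, Krt25 was at least 704-fold higher, Krtap6-5 at least 692-fold, Krtap19-9b at least 634-fold, Krt34 at least 633-fold and Krt87 at least 393-fold (adjusted p from 7.91e-05 to 0.0025). These bounds hold for the main scaling, and with normexp and quantile normalization the log2 changes of Krt25, Krtap6-5, Krtap19-9b, Krt34 and Krt87 were 8.05, 8.37, 8.32, 8.23 and 7.37. The fitted log2 change of Krt34 ran from 9.37 without WT replicate 1 to 10.95 without WT replicate 2. Keratins and keratin-associated proteins belong to families of near-identical genes, so single members are uncertain where probes cross-hybridise.

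All 11 measured hair shaft keratins rose, with a median log2 change of 8.40 (8.30 with the 6 members that were dim in WT at their bound). Of 42 measured keratin-associated proteins, 41 rose, with a median of 8.67 (7.32 with bounds). In the list of inner root sheath and companion layer genes, 9 of 12 rose (median 5.83, or 5.68 with bounds), among them Krt26 at least 56.0-fold. Regulators of the hair matrix and cortex rose in 14 of 21 cases (median 1.33, or 1.25 with bounds). S100a3, a calcium-binding protein of the hair cuticle, rose 83.3-fold. Dsg4, a desmosomal cadherin of the shaft, was at least 4.20-fold higher (no longer called without either cKO array, adjusted p = 0.057 and 0.058), with fitted log2 changes of 3.15 and 4.38 without WT replicate 1 and 2. Dlx4 was at least 2.78-fold higher and Shh, a growth signal of the hair matrix, at least 2.38-fold. With normexp and quantile normalization the log2 changes of Krt26, Dsg4, Dlx4 and Shh were 4.80, 1.45, 1.24 and 1.32. Each of these 4 lists lay at the 100th percentile of its random lists. Adjusted over the list alone, the counts were the same.

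**Figure D2:**
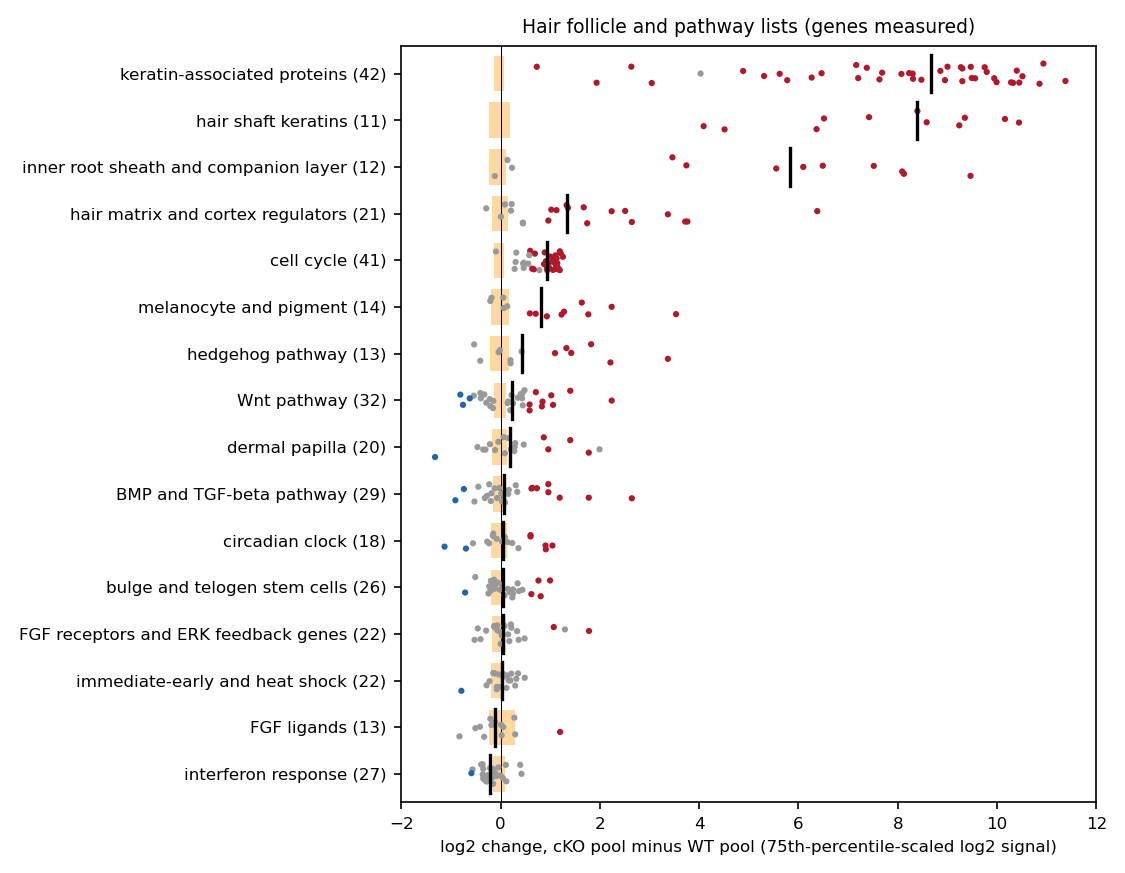
Log2 change (cKO pool minus WT pool, x axis) of each measured gene of the 16 pathway lists (rows, number measured in brackets); red points rose, blue points fell, grey points were not called, black lines are list medians and orange bands span the limits set by 10000 random list medians. The medians of keratin-associated proteins (8.67), hair shaft keratins (8.40) and inner root sheath genes (5.83) stand farthest from the bands.

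Proliferation and pigment genes were also higher in the cKO pool. Of 41 cell cycle genes, 31 rose and none fell (median 0.94, 100th percentile). Ccnb1, a mitotic cyclin, rose 2.39-fold, its partner kinase Cdk1 2.32-fold, the mitotic transcription factor Foxm1 2.29-fold and the spindle checkpoint kinase Bub1b 2.29-fold. Of 14 melanocyte and pigment genes, 9 rose (median 0.82, or 0.65 with bounds, 100th percentile). Trpm1, a channel of melanocytes, rose by log2 3.53 and was well above background on 1 of the 2 WT arrays. The melanosomal transporters Slc45a2 and Slc24a5 rose 3.40-fold and 3.11-fold, and Oca2 was at least 1.16-fold higher. Without cKO replicate 2, Slc45a2 was no longer called (adjusted p = 0.051). For Trpm1, Slc45a2 and Oca2, normexp and quantile normalization gave log2 changes of 2.32, 0.94 and 0.81. Adjusted over the list alone, both counts were the same.

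Among signalling lists, hedgehog and Wnt genes shifted upward. Of 13 hedgehog pathway genes 6 rose (median 0.42, 99.99th percentile), including the pathway's transcriptional targets Gli1 (3.54-fold) and Hhip (at least 2.19-fold). Hhip missed the fold threshold with normexp and quantile normalization (log2 0.57). Of 32 Wnt pathway genes 9 rose and 3 fell (median 0.24, or 0.18 with bounds, 99.99th percentile). Lef1, a transcription factor of the hair matrix, rose 4.72-fold, the Wnt antagonist Wif1 2.65-fold and the ligand Wnt10b 2.03-fold. The Wnt list holds ligands together with antagonists, and 20 of its genes were not called. Its median therefore does not show the activity of the pathway. Wnt5a was at least 1.09-fold higher at an adjusted p of 0.0499, a call that was lost under 8 alternatives. In the dermal papilla list 4 of 20 genes rose and 1 fell (median 0.18, 99.4th percentile). The BMP antagonist Nog rose 3.43-fold and Inhba, an activin subunit, 1.95-fold, while Crabp1, a retinoic acid-binding protein, fell 2.49-fold. In the BMP and TGF-beta list 8 of 29 rose and 2 fell (median 0.06, 95.7th percentile), with the largest rises in Msx2 (6.25-fold) and Nog, followed by Bambi (2.29-fold). The log2 change of Nog was 1.13 with normexp and quantile normalization. Adjusted over the list alone, these counts were the same.

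Few genes of the FGF pathway itself were called. Of 13 measured FGF ligands 1 rose, Fgf5 (2.30-fold, adjusted p = 0.00061), known as a signal that ends hair growth. The log2 values of the others included -0.83 for Fgf6 (adjusted p = 0.19), -0.51 for Fgf9, -0.41 for Fgf13, 0.30 for Fgf10, 0.28 for Fgf22, -0.11 for Fgf7 and -0.18 for Fgf1. Fgf2 and Fgf12 were well above background on 1 WT array, and Fgf6 and Fgf21 on 1 cKO array. The list median was -0.11 (15.0th percentile). Among 22 receptors and ERK feedback genes 2 rose, the ETS factor Etv4 (3.44-fold) and the FGF receptor-binding protein Flrt3 (2.10-fold), with a list median of 0.05 (86.7th percentile). The receptors had log2 values of 0.18 (Fgfr1), 0.21 (Fgfr2), 0.33 (Fgfr3) and -0.40 (Fgfr4). The feedback inhibitors Spry1, Spry2 and Dusp6 had -0.06, 0.0056 and 0.22, and Spry4 had -0.52 (adjusted p = 0.070; -0.73 and called without cKO replicate 1). Spred3, another feedback inhibitor, was at least 1.24-fold higher and dim in WT (adjusted p = 0.062, and 0.022 and called with trend and robust moderation). Probes of Fgfr1, Dusp4, Spred2 and Spry2 differed among themselves, from -0.49 to 0.19 for Fgfr1. The 2 probes of Fgf1, Fgf21 and Fgf22 gave -0.18 and 0.45, 0.02 and 1.57, and 0.28 and 0.73. With the mean of a gene's probes, the list medians changed sign (0.01 for ligands and -0.06 for receptors and feedback genes). Adjusted over the list alone, the counts were the same.

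Stem cell, clock, stress and interferon genes showed small or mixed changes. In the list of bulge and telogen stem cell genes 4 of 26 rose and 1 fell (median 0.05, 97.6th percentile). Cdh3, which encodes P-cadherin, rose 2.0-fold and Tbx1 1.70-fold. Runx1 rose 1.75-fold by its brightest probe, and another probe gave a log2 value of 0.05. Npnt fell 1.64-fold. With the mean of probes neither was called (0.43 for Runx1 and -0.55 for Npnt), nor was Npnt with normexp and quantile normalization (-0.57). The list did not stand apart under 5 alternatives. Of 18 clock genes 5 rose and 2 fell (median 0.06, 87.2nd percentile). The list holds activators as well as repressors and outputs, so opposite changes can cancel in this median, which cannot show a shift in clock time. Per1, Dbp and Nr1d2, which are clock-controlled repressors or outputs, rose 2.06-fold, 1.88-fold and 1.87-fold. Npas2, a partner of the activator Bmal1, fell 2.18-fold, a call lost in 6 settings and measured well above background on 1 cKO array. Of 22 immediate-early and heat shock genes 1 fell, Fosb (1.73-fold, not called without either cKO array, adjusted p = 0.059 and 0.054, nor with normexp and quantile normalization, log2 -0.43), and the median was 0.04 (97.0th percentile). Of 27 interferon response genes 1 fell, Rsad2 (log2 -0.59, not called without cKO replicate 1 or WT replicate 2, with log2 values of -0.56 and -0.57, nor under 3 other scalings, with values from -0.55 to -0.53), and the median of -0.21 lay at the 0.25th percentile. Adjusted over the list alone, these counts were the same.

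Fewer of the genes lower in the cKO pool passed 2-fold. Among genes well above background on all 4 arrays, the largest fall was that of Angptl8, a lipid- and feeding-regulated secreted protein (10.4-fold, adjusted p = 0.00011; chromosome 9, from 21641539 on mm9). Myh3, the embryonic myosin heavy chain, fell 8.13-fold, Ankrd1, a muscle ankyrin repeat protein, 4.58-fold, Slc26a7, an anion transporter, 4.54-fold, Thrsp, a regulator of lipid synthesis, 4.13-fold, Pttg1, encoding securin, 3.86-fold, and Olfr1065, an olfactory receptor gene, 3.25-fold. With normexp and quantile normalization the log2 changes of Myh3, Ankrd1, Slc26a7, Stc1 and Plcz1 shrank to -1.91, -1.16, -1.54, -1.26 and -1.50, and those of Rab39b, Gad2 and Bcl2l10, named below, were -1.48, -1.14 and -0.70. Plcz1 fell 5.27-fold with a large error (log2 -2.40, SE 0.57) and lost its call without either cKO array (adjusted p = 0.13 and 0.14), without the filter on dim probes (0.11) and with trend and robust moderation (0.060). Without WT replicate 1 its log2 change was -1.66 and without WT replicate 2 it was -3.14. Probes disagreed for Rrp7a (log2 -2.31 and -0.06) and Stc1 (-1.93 and 0.55). Of genes not well above background on either cKO array, Rab39b was at least 5.19-fold lower, Gad2 at least 4.09-fold, Bcl2l10 at least 3.27-fold and P2ry10b at least 2.41-fold. P2ry10b missed the fold threshold with normexp and quantile normalization (log2 -0.53). The fitted log2 change of Rab39b ran from -5.39 to -3.62 and that of Gad2 from -4.70 to -2.43 when single arrays were left out. Rab39b was no longer called without either cKO array, and neither Gad2 nor Bcl2l10 was called without either WT array. None of the 3 was called without the filter on dim probes (adjusted p = 0.075, 0.12 and 0.052).

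Lists of muscle, fat, sebaceous gland, vessel and nerve markers had negative median changes in the cKO pool, although most genes in each were not called. Of 23 skeletal muscle genes 11 fell (median -0.52, 0.00th percentile), including Neb (1.82-fold), Casq1 (1.79-fold), Myoz1 (1.69-fold) and Actn3 (1.69-fold), which encode sarcomere or calcium-store proteins. Myoz1 was not called with quantile normalization (log2 -0.57). Of 18 adipocyte genes 5 fell (median -0.29, 1.03rd percentile), among them Gpd1 (2.39-fold), the hormone Lep (1.97-fold) and the glucose transporter Slc2a4 (1.69-fold). The adipocyte list lay inside its random range with normexp and quantile (-0.14) and with quantile normalization (-0.15). Of 18 sebaceous gland genes 4 fell and 1 rose (median -0.34, 0.19th percentile). Fasn, the fatty acid synthase, fell 1.94-fold, Soat1 1.64-fold and Dgat2 1.57-fold (log2 -0.45 and not called with normexp and quantile normalization or with quantile normalization), while the desaturase Fads2 rose 3.43-fold. Of 12 smooth muscle and pericyte genes 3 fell (median -0.26, 1.89th percentile). Of these, Des fell by 0.68 on the log2 scale, and the other probes of Acta2 and Synpo2 reached 0.02 and 0.49 against -0.76 and -0.61 for the brightest. With the mean of probes Acta2 and Synpo2 were not called (-0.20 and -0.23), nor were they with normexp and quantile (-0.54 and -0.51) or quantile normalization (-0.53 and -0.54) or, for Synpo2, under 2 other scalings (-0.58 and -0.55), and the list lay inside its random range (-0.24), as it did without cKO replicate 1 (-0.25). Of 15 endothelial genes Emcn and Lyve1 fell 1.73-fold and 1.66-fold (median -0.29, 0.23rd percentile); Lyve1 was not called with the mean of probes (-0.55). Of 11 nerve and Schwann cell genes 2 fell, among them the myelin gene Mbp (1.63-fold), with its probes between -0.95 and -0.18 (median -0.41, 0.00th percentile). Adjusted over the list alone, these counts were the same.

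The remaining cell type lists were mixed. Of 14 basal epidermis genes only Cdh3 rose (median 0.14, 99.98th percentile). Of 27 genes of differentiated epidermis 3 rose and none fell, while the median was -0.28 (0.39th percentile). Those that rose were Rptn (3.64-fold) and Tgm3 (2.43-fold), both also known from the hair follicle, and Krt2 (1.55-fold), which was not called without cKO replicate 1, cKO replicate 2 or WT replicate 1, nor with normexp and quantile normalization (log2 0.38). In the epidermal stress and wound list 4 of 15 rose and 4 fell (4 and 5 adjusted over the list alone, median -0.01, 78.5th percentile). Sprr2h rose 6.26-fold, Sprr1a 3.64-fold, Krt16 3.40-fold and Krt6a 2.10-fold. The log2 change of Sprr2h, 2.65, was 1.93 with normexp and quantile normalization. Of 8 mast cell genes 2 fell, Cma1 (1.61-fold) and Fcer1a (1.53-fold, log2 -0.53 and not called without cKO replicate 2), neither called with normexp and quantile normalization (-0.57 and -0.27) and Fcer1a not under 2 other scalings (-0.58 and -0.56), and Hdc rose 2.01-fold (median -0.42, 0.13th percentile). Of 20 dermal fibroblast genes Dpt rose 1.70-fold and Lum fell 1.55-fold (log2 -0.43 and not called with normexp and quantile normalization, nor with quantile normalization, -0.44, or scaling over genes not called higher, -0.57; median -0.18, 15.1st percentile). None of 19 macrophage and dendritic cell genes was called (median -0.08, 63.0th percentile), and their brightest members had log2 values of -0.11 (Lyz2) and 0.29 (H2-Ab1). Of 14 T cell genes 1 rose, Cd4 (at least 3.81 log2 units, median of the list 0.15, 94.2nd percentile). Of 6 red cell genes 2 rose, Ahsp (at least 6.39-fold) and Slc4a1 (at least 5.34-fold), with a median of -0.14 (32.0th percentile). The log2 changes of Cd4, Ahsp and Slc4a1 were 2.54, 2.03 and 1.51 with normexp and quantile normalization. Apart from the stress list, counts adjusted over the list alone were the same.

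**Figure D3:**
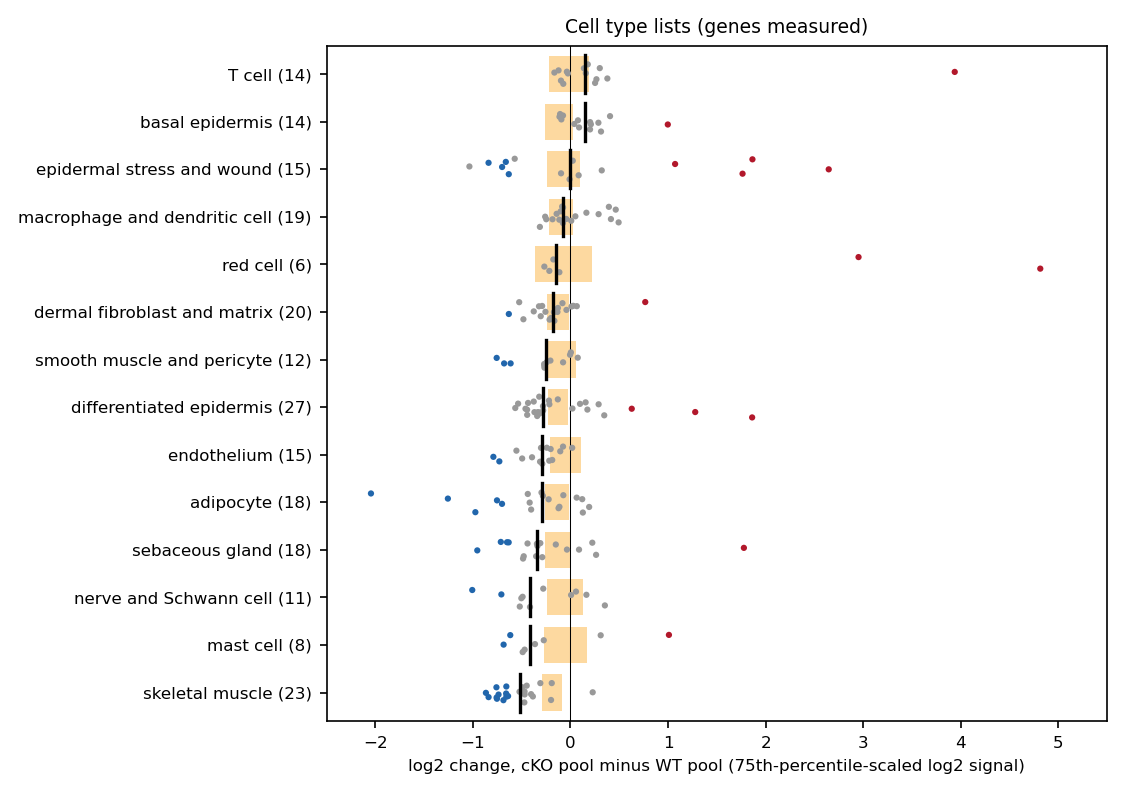
Log2 change (cKO pool minus WT pool, x axis) of each measured gene of the 14 cell type lists (rows, number measured in brackets), with points, black median lines and orange random bands as in the plot of pathway lists. The skeletal muscle median, -0.52, is the lowest, and the single points farthest right are Ahsp, Cd4 and Slc4a1, each dim in WT and drawn at its fitted value.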

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

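The scaling over genes not called higher and the limit of 0.5 log2 between duplicates were chosen after seeing the data. Over settings at the same thresholds, 718 to 1123 genes rose and 481 to 916 fell. The lowest count of falls, 481, came with normexp and quantile normalization. A 2-fold threshold gave 515 and 150, and adjusted p alone 3890 and 5907. The replicate block gave 986 and 829 calls, of which 964 and 809 were shared with the fit without it. Same-numbered arrays did not deviate together (r = -0.043), so the numbers were not taken as pairs. Fgf18 stayed between -0.34 and -0.25 and was called in no setting that kept a fold threshold. By limma adjusted p alone (0.0035 in the main fit) it passed. Without the filter on dim probes, the median of all genes was -0.16. Of the list medians under alternatives, 463 kept their side of the limits. The bulge list fell within its random range with normexp and quantile normalization (0.060), quantile normalization (0.078), probes well above background on all arrays (0.027) and the mean of probes (0.0076), and ranged from 0.017 to 0.069 when single arrays were left out. The BMP list moved outside with normexp (0.087) and the mean of probes (0.062). The immediate-early list did so with normexp (0.13), quantile (0.12) and the mean of probes (0.038), with a range of 0.024 to 0.045 over left-out arrays. The fibroblast list did so with the mean of probes (-0.29). The adipocyte list moved inside with normexp (-0.14) and quantile (-0.15). Smooth muscle moved inside with the mean of probes (-0.24), with a range of -0.26 to -0.25 over left-out arrays. The cause was not tested. Of the named genes' values under alternatives, 2149 kept their direction and side of the threshold, 70 lost a call, 6 gained one and 1 reversed. The last was Fgf21, from -0.65 to 0.70 over left-out arrays, with 1 cKO array well above background. Counted per gene, 82 of the 104 called named genes kept their call under every scaling, filter and probe setting. Fosl1 was called without WT replicate 2 (-0.77). Signal over background limits genes that are dim in 1 pool. Their change in the main fit is given as a bound, while fitted values appear where settings are compared, in list medians and in plots. A slide block could not be fitted with 1 slide.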

Other observations

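The lists in this part were drawn up after the main results were seen. All tests here except the percentile limit of the fasting-induced list were chosen after the result was seen. The lists hold genes whose changes prompted them (Thrsp and Angptl8, Myh3 and Ankrd1), so counts and values in this paragraph are given without a test. Genes of fatty acid synthesis were lower in the cKO pool, where 10 of 17 fell and none rose (median log2 change -0.63). Scd2 fell with a log2 change of -1.01, Acaca, the first committed enzyme of fatty acid synthesis, with -0.99, and the lipogenic transcription factor Srebf1 with -0.61. Of 19 cholesterol synthesis and uptake genes 2 fell, among them Insig1 (-1.05), and 18 had values below 0 (median -0.32). Of 14 genes of immature or denervated muscle 7 fell (median -0.50), among them Myh3 (-3.02), Chrna1 (-1.09) and Myod1 (-1.01). The skeletal muscle list had a similar median (-0.52, 11 of 23 fell), so this median does not set immature muscle genes apart from muscle genes in general. None of 14 polyamine and nucleolus genes was called (median 0.16). The medians of the fatty acid, cholesterol, immature muscle and polyamine lists kept their sign under 6 other scalings.

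The 72 probes of shaft keratins, keratin-associated proteins and root sheath genes held 1.56% of the summed signal on each cKO array and 0.076% and 0.078% on the WT arrays. Cd4, Ahsp and Slc4a1 were at least 3.81, 2.68 and 2.42 log2 units higher in cKO, while the other members of their lists were not called. Hdc and Fads2 rose while other called members of the mast cell and sebaceous gland lists fell.

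The higher level of growing-follicle genes in a pool labelled telogen was weighed first. The scaling or background correction of the arrays is argued against, since the median of the hair shaft keratins was at least 7.37 under every scaling and background setting tried. Scaling by 1 number per array moves all genes alike and could hardly remove the rise, so only normexp and quantile normalization tested it. The share of the 72 hair probes in the summed signal, which such scaling leaves unchanged, was 1.56% on each cKO array against 0.076% and 0.078% on the WT arrays. Growing hair follicles in the mice of the cKO pool stay open, as a count of the hair lists would only restate the pattern. The separately fixed cell cycle list (31 of 41 rose, 10 not called) and pigment list (9 of 14 rose, 5 not called) also shifted upward. A growing stage of the follicles was, however, not observed directly. Whether such a stage follows from the deletion, or is a stage difference between these mice that is not due to the deletion, cannot be told apart with 1 pool per genotype.

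The lower level of lipid synthesis genes was weighed second. Fewer adipocytes in the cKO pool stay open, since the values go both ways: the adipocyte list had a median of -0.29 (inside its random range with normexp and quantile, -0.14, and with quantile normalization, -0.15), and 12 of its genes outside lipid synthesis, a choice that left out called genes, had -0.12, with Adipoq at -0.11 and Fabp4 at 0.19, against -0.63 for the synthesis list. Tests of the adipocyte genes against the synthesis list, in 3 forms, were dropped because the synthesis list was drawn up around genes that fell. A less fed state of the cKO mice when skin was taken stays open. The fasting-induced list passed the limit set beforehand for it (99.6th percentile of random lists, 6 of 18 rose and none fell, among them Angptl4 with 1.95). Its median of 0.11 was near 0, however, and 8 members lay below 0, such as Cpt1b (-0.23) and Acadm (-0.21). A 95% bootstrap interval over its genes, taken as independent, ran from -0.10 to 0.62. This interval was no part of the limit set beforehand, by which alone the list goes with a less fed state. Only that limit was set beforehand, whereas the genes of the list were chosen after the main results were seen. Different clock times of collection and an effect of the deletion stay open without a test, as a split of the clock genes made after their signs were seen was dropped.

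A chromosome segment of another strain around the targeted gene was weighed last, as a possible source of called genes on both sides of Fgf18. Within 10 Mb of it, 10 of 61 genes were called (16.4%, against a median of 9.92% in 1889 windows around other genes). Pttg1, one of the 10 largest falls (log2 -1.95), lies just outside this window and is not counted. This share lay at the 90.8th percentile of those windows, between the limits set for it and against it, so the segment cannot be told apart from the other changes with these data.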
